A study of Mus musculus with 6 samples.

How the data were processed

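RNA was sequenced from whole livers of 3 control mice, which carry floxed Notch1 alleles, and 3 mice in which Notch1 was deleted in hepatocytes. Per the labels' protocols, RNA was isolated with Trizol, messenger RNA was taken on poly-T beads and libraries were made with a NEBNext Ultra RNA kit; strand, sex, age, diet and time of collection are not given in the sources used here. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mouse genome build GRCm38, without saying how each was set. Groups and replicate numbers were taken from the sample labels. Knockout columns carry the group's name, while the control columns are named NC and were taken as the controls by elimination, with the number as the replicate (0 columns left over); every control value rests on this inference. Nothing in the labels states how the mice were housed or paired, so the p-values measure the spread among these 6 livers.

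The table the authors deposited holds FPKM (fragments per kilobase of gene length, scaled for library size) for 54532 genes, with gene names, coordinates, biotypes and gene lengths. How FPKM was computed is not stated, so its construction was read from the values. FPKM times gene length was a whole multiple of 1 step per library, within 0.1 read, for 100% of values above 0. The whole reads recovered this way summed to 16053926, 16795674 and 16809352 in controls 1 to 3 and to 15612924, 17511961 and 15807542 in knockouts 1 to 3. The divisor in each library was not the read total. It equalled the median ratio of reads to the geometric mean over libraries, times a constant, with factors of 0.914, 0.976 and 1.01 in the controls and 0.911, 1.22 and 1.04 in the knockouts. Scaling between libraries was therefore already part of the deposited FPKM values. At these depths 3 reads in a gene 1 kilobase long correspond to 0.150 to 0.201 FPKM, so lower levels may read as 0. By gene identifier, 54409 of the genes were found in the GENCODE M21 annotation of GRCm38 and 53499 had the same coordinates. Coordinates below are those of the file.

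Genes with a mean of at least 0.5 FPKM over the 6 libraries (12022) were tested on log2(FPKM + 1) with limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3, knockout against control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A pseudocount of 1 understates the change of genes with low values, so ratios of mean FPKM are given beside log2 fold changes. Errors are SD over n = 3 libraries unless marked SE. Before the data were examined, 46 gene lists were fixed from textbook liver biology, Notch signalling and markers of other cells in liver. The 44 lists with at least 5 tested genes were tested with limma's camera, preset correlation 0.01, with adjustment over the lists, and again with the correlation estimated per list and with fry, both for a shared direction and for changes in either direction (mixed). Each gene's p was also adjusted over its list alone. Named genes followed a rule set before the data were examined: Notch1 and Thpo; per direction the 12 genes with the largest change past the threshold, filled up by the smallest p, with at least 1 FPKM in the higher group, no overlap between groups and no predicted gene models; then the 4 members with the smallest p in the direction of each list that passed, up to 3 of other lists, and any member of the Notch and thrombopoietin lists. Genes named outside this rule are marked as chosen after their values were seen. A list of 22 mesothelial markers was written after the values were seen.

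The replicate numbers of the 2 groups were checked for pairing. Deviations from the group means correlated across genes at 0.31, 0.16 and 0.10 for same-numbered libraries 1, 2 and 3, each above 0.1, and at -0.25 to 0.11 for libraries with different numbers. The ranges overlapped: control 3 and knockout 2 correlated at 0.11, above same-numbered pair 3. This evidence is weak and comes from the values alone, since the labels give no shared litter, batch or day. The numbers were therefore used as pairs only in an alternative fit. The model fixed in advance has no block; values with the replicate number as a block are printed where they change a call.

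The fit was tested on simulated reads for the 12022 genes, with 200 genes changed. It recovered 0% of genes changed 1.5-fold and 27.0% of genes changed 2-fold, with 3 false among 57 calls. Of genes changed 4-fold it recovered 95.5%, with 19 false among 210 calls, and with no gene changed it called 0. Simulated genes of like level shared the same spread between livers, which real genes need not, so these rates may not hold for the real data. The results were refitted under 19 alternatives: pseudocounts, filters on low values, scaling, weights, settings of eBayes, the replicate block and leaving out each library. A limma voom fit on the recovered reads and scaling by total reads were chosen after the data were seen. Reads of near-identical copies (Saa1 and Saa2, Hba-a1 and Hba-a2, the Mup, Cyp2c and Cyp4a families, mitochondrial genes with nuclear copies) and of overlapping genes, such as those of the Ugt1a locus, may be split between genes by the authors' counting, so single values in these families are uncertain.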

Results

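Whole-liver messenger RNA was compared between 3 control mice with floxed Notch1 and 3 mice lacking Notch1 in hepatocytes, a design made to ask what Notch1 does in the liver's production of thrombopoietin, the hormone that drives platelet formation. The libraries held 15612924 to 17511961 reads in genes. Levels are FPKM, given as mean ± SD over 3 livers per group.

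Notch1 itself measured lower in each knockout liver than in any control. The gene (ENSMUSG00000026923, chromosome 2, 26457903 to 26516663, GRCm38) measured 0.812 ± 0.177 FPKM in controls and 0.377 ± 0.141 in knockouts (SD, n = 3), a ratio of 2.15. All 3 knockouts (0.301, 0.540 and 0.292) lay below all 3 controls (0.618, 0.965 and 0.854), with 132, 220 and 202 reads in the controls and 64, 154 and 71 in the knockouts. The difference did not pass the threshold (log2 fold change -0.40, 95% interval -0.70 to -0.10, limma adjusted p = 0.257, and 0.135 to 0.477 over the alternatives). A gene-level value adds all exons and all liver cell types, so it does not measure the deleted part in hepatocytes.

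Thpo, which encodes thrombopoietin (ENSMUSG00000022847, chromosome 16, 20724454 to 20734511), measured 4.44 ± 1.17 FPKM in controls and 3.54 ± 0.921 in knockouts, and the groups overlapped. Its log2 fold change was -0.26 (95% interval -0.76 to 0.24, adjusted p = 0.632), at a depth of 131 to 217 reads. Within each same-numbered pair Thpo was lower in the knockout (5.50 and 3.92, 3.18 and 2.49, 4.63 and 4.21 FPKM), and with the replicate number as a block the same log2 change had an SE of 0.10 in place of 0.21 (adjusted p = 0.302, the lowest of a range up to 0.914 over the alternatives). Asgr1 and Asgr2, the subunits of the asialoglycoprotein receptor that takes up desialylated platelets, measured 292 ± 6.25 and 104 ± 10.5 FPKM in controls against 246 ± 23.1 and 76.6 ± 12 in knockouts (adjusted p = 0.396 and 0.267). Il6ra, the interleukin 6 receptor, measured 2.94 ± 0.368 against 5.28 ± 0.723. Socs2 and Cish, feedback inhibitors of JAK-STAT signalling, measured 7.25 ± 3.78 against 1.66 ± 0.572 and 3.99 ± 0.991 against 0.383 ± 0.0768. Of the 18 tested genes of thrombopoietin control and JAK-STAT signalling, 9 had higher and 9 lower means. Cish fell over all genes tested, and 1 gene (Il6ra) rose and 2 (Cish and Socs2) fell when adjusted over the list alone. As a set the list did not differ from other genes (camera adjusted p = 0.781), with a median log2 change of 0.0046 and a mean of -0.13.

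**Figure D1:**
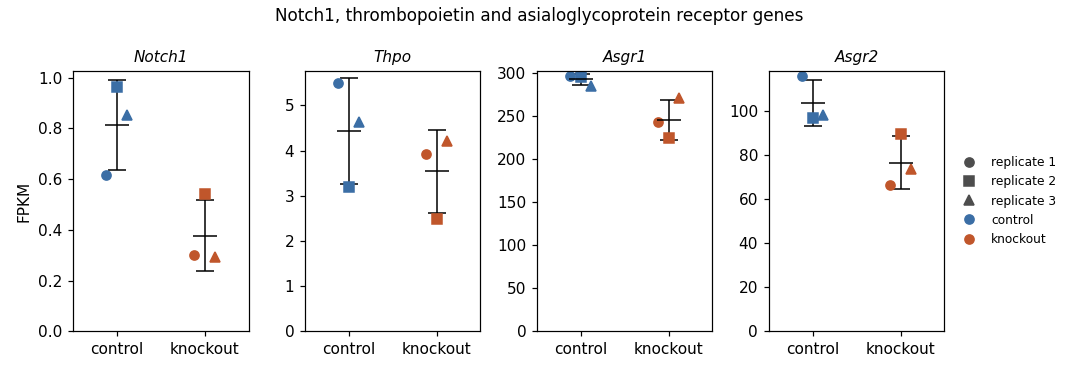
Expression in FPKM (vertical axis) of Notch1, Thpo, Asgr1 and Asgr2 in 3 control and 3 knockout livers, one marker per liver, with horizontal bars for the mean and error bars for the SD. Notch1 ranged from 0.618 to 0.965 in controls and from 0.292 to 0.540 in knockouts, while the Thpo values of the groups overlapped.

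Other members of the Notch pathway showed smaller differences. Jag1, a Notch ligand, measured 0.637 ± 0.0816 FPKM in controls and 0.445 ± 0.0332 in knockouts, and Rbpj, the DNA-binding partner of Notch, 0.738 ± 0.121 against 1.03 ± 0.165. Notch2 values overlapped. Of the 20 pathway genes tested, 11 had higher and 9 lower means, and 0 passed over all genes or adjusted over the list alone. Among 12 tested Notch target genes, Sox9 rose (0.735 ± 0.174 to 1.49 ± 0.330) and Myc fell (4.77 ± 2.02 to 1.64 ± 0.486) when adjusted over the list alone (adjusted p = 0.042 for each), and 0 passed over all genes. Hes1, a direct Notch target, measured 3.25 ± 1.23 in controls and 5.27 ± 0.789 in knockouts, with overlapping values. Neither list stood apart from other genes (camera adjusted p = 0.826 for the pathway and 0.136 for the targets).

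Across the transcriptome, 3 of the 12022 genes passed the threshold. Bcl6, a transcriptional repressor (chromosome 16, 23965052 to 23988852), rose 6.09-fold, from 1.43 ± 0.541 to 8.69 ± 0.822 FPKM (log2 fold change 2.02, SE 0.17). Cish (chromosome 9, 107296026 to 107302784) fell, with means 10.4 times apart (log2 fold change -1.84, SE 0.15). Wdfy1, an endosomal adaptor protein (chromosome 1, 79702262 to 79776143), fell from 4.69 ± 0.266 to 0.571 ± 0.266 FPKM (log2 fold change -1.87, SE 0.14). Each had an adjusted p of 0.0252, and all 3 knockouts lay outside the controls. With the replicate number as a block, the adjusted p of each was 0.0549 and 0 genes passed, with 84 genes at an adjusted p under 0.10 against 21 without the block. Over the 19 alternatives the adjusted p ranged from 0.00969 to 0.171 for Bcl6 and Cish and from 0.00969 to 0.124 for Wdfy1. Leaving out single livers ended all 3 calls without control 2 (0.0904) and without knockout 1 (0.0665 for Bcl6 and Cish, 0.0516 for Wdfy1). It ended those of Cish and Wdfy1 without control 1 (0.0830) and those of Bcl6 and Cish without knockout 3 (0.171). At an unadjusted p under 0.05 there were 1670 genes, 821 higher and 849 lower, where chance gives 601 and the other splits of the 6 livers gave at most 891, and the groups did not overlap in 19.8% of genes, where chance gives 10%.

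**Figure D2:**
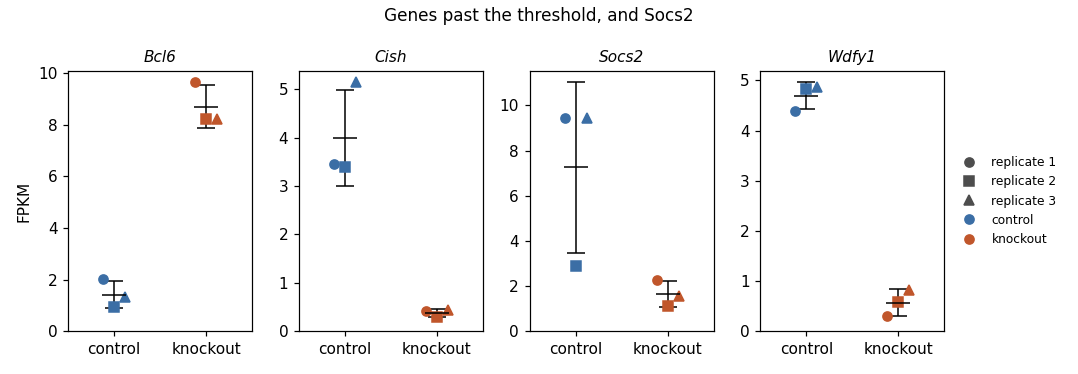
Expression in FPKM (vertical axis) of Bcl6, Cish and Wdfy1, the genes past the threshold, and of Socs2, in 3 control and 3 knockout livers, one marker per liver, with the mean and SD. Bcl6 lay at 8.21 to 9.64 in the knockouts against 0.941 to 2.01 in the controls, and Cish at 0.295 to 0.437 against 3.38 to 5.14.

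The remaining named genes did not pass the threshold and are given as values. Among those higher in the knockouts, Mt2, a metallothionein, measured 1.33 ± 0.982 FPKM in controls and 31.0 ± 16.2 in knockouts. Saa3, a serum amyloid, measured 1.23 ± 0.337 against 5.19 ± 1.19. Slc3a1, an amino acid transporter subunit, measured 6.37 ± 0.894 against 19.0 ± 4.30, and Angptl8, a hormone induced by feeding, 23.4 ± 5.33 against 55.8 ± 8.62. Tfrc, the transferrin receptor, measured 2.26 ± 0.518 against 5.35 ± 0.262. Selenom, Myo5b, Tpm4 and Slc39a8 differed by ratios of 2.30, 1.72, 1.68 and 1.96. Il18r1 (0.303 ± 0.330 against 2.89 ± 0.568) and Barx1 (0.146 ± 0.136 against 1.63 ± 0.487) were low in controls, and control 3 had the highest control value of both (0.675 and 0.301). The adjusted p of these 11 genes lay between 0.0877 and 0.105.

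Among the genes lower in the knockouts, Alas1, the first enzyme of heme synthesis, measured 43.4 ± 16.3 FPKM in controls and 9.23 ± 1.44 in knockouts. Hhex, a hepatocyte and endothelial transcription factor, measured 42.4 ± 5.67 against 19.1 ± 1.27. Phlda1 measured 20.1 ± 2.70 against 6.29 ± 1.51, and Ces1g, a carboxylesterase, 107 ± 7.31 against 50.8 ± 4.77. Enpp2, which encodes autotaxin, measured 9.64 ± 0.852 against 5.34 ± 0.271. Slc17a8, Olig1 and Ugt1a6b had control means 2.35, 2.68 and 1.77 times those of the knockouts. The mitochondrial tRNA gene mt-Tm (14.0 ± 1.22 against 2.54 ± 1.49) rested on 2 to 17 reads per library. The adjusted p of these genes lay between 0.0877 and 0.0998.

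By camera, 7 of the 44 gene lists were higher in the knockouts and 12 were lower. Other splits of the 6 livers into 3 and 3 gave 7 to 21 lists by the same test, so the count of 19 does not stand out. None of the 19 passed with an estimated correlation between genes or by fry's test of a shared direction, which called 0 lists; the estimated-correlation p is given beside each list. By fry's mixed test, which asks whether genes of a list change in either direction and does not compare the list with other genes, 17 of the 44 lists passed. Among them were 6 of the 19: growth hormone and IGF (adjusted p = 0.000223), cholesterol synthesis (0.0011), fatty acid oxidation (0.00968), hepatocyte identity (0.00968), bile duct and progenitor genes (0.00968) and bile acids (0.0157). The thrombopoietin and JAK-STAT list passed it too (0.000705), as did the Notch targets (0.0119). Cish and Socs2 are on both the thrombopoietin and the growth hormone list, and Thpo itself did not pass over all genes (limma adjusted p = 0.632). In 6 of the 19 the call held in all 19 refits: cholesterol synthesis, fatty acid oxidation, bile acids, growth hormone and IGF, the mitochondrial genome and the acute phase. With the replicate number as a block, bile duct and progenitor genes no longer passed (adjusted p = 0.0780, against 0.0335 without it), while immediate early genes (0.0182), glucose metabolism (0.0388) and neutrophil markers (0.0388) did.

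**Figure D3:**
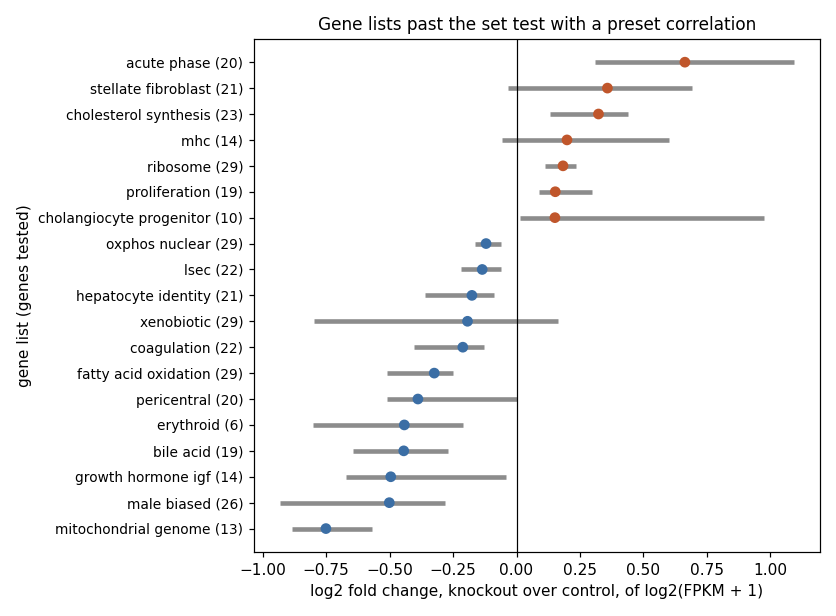
Median log2 fold change (points; horizontal axis, knockout over control, of log2(FPKM + 1)) and quartiles (bars) of the 19 gene lists that passed camera with a preset correlation, with the number of genes tested in brackets. Acute phase genes had the highest median, 0.66, and genes of the mitochondrial genome the lowest, -0.75.

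Genes of the growth hormone and insulin-like growth factor axis were lower in the knockouts as a set. Of 14 tested, 12 had lower means and the median log2 change was -0.50 (camera adjusted p = 0.00605; adjusted p = 0.431 with an estimated correlation); without knockout 1 the median was -0.28. Cish, a growth hormone target, was the member that fell over all genes, and Bcl6, which growth hormone represses in liver, was the one that rose. Adjusted over the list alone, 7 fell and 1 rose. Besides Cish and Socs2, these include Igfals, which carries IGF1 in blood (44.5 ± 6.22 FPKM in controls, 26.3 ± 6.53 in knockouts), and Ghr, the growth hormone receptor (61.8 ± 7.33 against 41.2 ± 6.54). Stat5b, the main signal transducer of growth hormone in liver, chosen after its values were seen, measured 11.5, 12.3 and 13 in controls and 11.9, 13 and 13.4 in knockouts.

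Male-biased genes, many of which depend on pulsed growth hormone, were lower as a set (24 of 26 with lower means, median log2 change -0.50, adjusted p = 0.00107; adjusted p = 0.667 with an estimated correlation). The named members were Mup2 (21.1 ± 1.54 against 9.77 ± 3.75 FPKM), Cyp4a12a (189 ± 28.0 against 86.4 ± 40.4), Slco1a1 (149 ± 13.5 against 100 ± 33.1) and Cyp2f2 (492 ± 76.2 against 366 ± 48.0), and 0 passed when adjusted over the list alone. Knockout 2 stood apart: the median log2 difference of the list from the control mean was -1.53 in that liver, against -0.0066 in knockout 1 and -0.22 in knockout 3. Hsd3b5, chosen after its values were seen, measured 14.0 in knockout 2, 193 and 106 in the other knockouts and 192 to 243 in controls. Without knockout 2 the list did not pass (adjusted p = 0.335, the highest of a range from 2.07e-07 over the refits), with a median of -0.07, and without knockout 1 the median was -0.90. Female-biased genes did not stand apart with all livers (adjusted p = 0.850), but without knockout 2 they were lower as a set (median -0.37, adjusted p = 0.00994, the lowest over the refits, where the highest was 0.987). All 6 livers expressed the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, chosen after their values were seen, the tested members of a list too small for camera.

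Genes of cholesterol synthesis were higher in the knockouts. Of 23 tested, 19 had higher means, the median log2 change was 0.32 (adjusted p = 1.68e-06; adjusted p = 0.431 with an estimated correlation), and 8 rose when adjusted over the list alone, 0 over all genes. Hmgcs1 (47.5 ± 2.49 to 69.5 ± 3.14 FPKM), Idi1 (28.3 ± 2.26 to 44.5 ± 7.53) and Srebf2 (5.84 ± 0.503 to 8.09 ± 0.341), the transcription factor that drives this pathway, were among the 8. Genes of fatty acid synthesis did not stand apart (14 of 23 with higher means, adjusted p = 0.942).

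Fatty acid oxidation genes, many of them targets of PPARα, were lower. Of 29 tested, 26 had lower means, with a median log2 change of -0.32 (adjusted p = 1.68e-06; adjusted p = 0.595 with an estimated correlation). Adjusted over the list alone, 7 fell and 1 (Ucp2, chosen after its values were seen) rose, and 0 changed over all genes. Cyp4a10 had the smallest p (230 ± 27.9 against 97.4 ± 23.8 FPKM), followed by Vnn1 (21.6 ± 0.583 against 12.9 ± 3.82), Hadha (43.2 ± 2.44 against 34.3 ± 0.714) and Angptl4 (82.2 ± 9.83 against 52.9 ± 11.6). By fry with the replicate block this list passed (adjusted p = 0.00441).

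Bile acid genes were lower as well (17 of 19 with lower means, median log2 change -0.44, adjusted p = 3.45e-05; adjusted p = 0.431 with an estimated correlation). Slc10a1, the bile acid uptake transporter (201 ± 19.5 against 126 ± 16.5 FPKM), Cyp8b1, which sets the share of cholic acid (175 ± 9.30 against 95.5 ± 27.4), Abcc3 (31.8 ± 4.96 against 19.3 ± 4.05) and Cyp27a1 (195 ± 18.8 against 143 ± 14.7) were among the 6 that fell when adjusted over the list alone. Slc51b, a bile acid exporter chosen after its values were seen, rose by the same measure, from 0.181 ± 0.0987 to 1.20 ± 0.55, and 0 genes of the list changed over all genes. Cyp7a1, the rate-limiting enzyme of the classical pathway, chosen after its values were seen, measured 9.10, 15.5 and 10.8 in controls and 17, 11 and 6.03 in knockouts.

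Hepatocyte identity genes were lower as a set (17 of 21 with lower means, median log2 change -0.18, adjusted p = 0.00875; adjusted p = 0.609 with an estimated correlation). The 4 that fell when adjusted over the list alone were all transcription factors: Onecut1 (9.0 ± 4.35 to 1.06 ± 0.639 FPKM), Foxa1 (8.02 ± 1.60 to 3.46 ± 0.320), Foxa2 (12.9 ± 2.66 to 6.18 ± 1.22) and Cebpa (163 ± 18.7 to 107 ± 14.5). None of these passed over all genes, and quantile normalization ended the set's call (adjusted p = 0.179, from 0.00155 over the refits). Coagulation factor genes were also lower (19 of 22 with lower means, median -0.21, adjusted p = 0.000251; adjusted p = 0.609 with an estimated correlation). Klkb1 (29.9 ± 3.33 to 19.0 ± 1.29) and F11 (30.6 ± 4.29 to 20.9 ± 1.19) fell when adjusted over the list alone, and Proc and F5 had control means 1.33 and 1.34 times those of the knockouts. Without knockout 2 the coagulation call was lost (adjusted p = 0.0593, from 1.38e-06 over the refits), and without knockout 1 the median was -0.35.

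Genes expressed around the central vein were lower (15 of 20 with lower means, median log2 change -0.39, adjusted p = 0.0192; adjusted p = 0.609 with an estimated correlation), as were genes of drug metabolism (18 of 29, median -0.19, adjusted p = 0.0384; adjusted p = 0.609 with an estimated correlation). Cyp2e1 measured 1795 ± 106 FPKM in controls and 955 ± 327 in knockouts, Cyp27a1 195 ± 18.8 against 143 ± 14.7, Cyp2c29 416 ± 47.6 against 245 ± 97.0 and Cyp1a2 258 ± 59.0 against 152 ± 52.7. Cyp2c54 (189 ± 29.7 against 78.1 ± 38.8), Cyp2c50 (369 ± 42.8 against 184 ± 102) and Ugt1a1 (27.5 ± 3.4 against 20.4 ± 2.74) were the other drug metabolism genes with the smallest p, and 0 genes of either list passed when adjusted over the list alone. The pericentral call was lost without knockout 2 (median -0.14, adjusted p = 0.130, from 0.000439 over the refits), without control 2 (0.0931) and with quantile normalization (0.0688). The median of drug metabolism was -0.41 without control 1 and -0.34 without knockout 2. Its call was lost without knockout 3 (median -0.05, adjusted p = 0.257, from 0.000832), control 2 (0.167) or control 3 (0.117), with quantile normalization (0.128) and with a filter at 1 FPKM (0.0533). Genes expressed around the portal vein did not stand apart (adjusted p = 0.670).

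Acute phase genes, which the liver expresses in inflammation, were higher as a set (18 of 20 with higher means, median log2 change 0.66, adjusted p = 0.000294; adjusted p = 0.609 with an estimated correlation), and the difference came from 2 of the 3 knockouts. Saa2 measured 813 FPKM in knockout 1 and 1537 in knockout 3, but 8.62 in knockout 2, against 12.2, 4.79 and 3.94 in the controls. Saa1 measured 1023, 16.2 and 1596 in knockouts 1 to 3 and 12.8 to 41.9 in controls. Hp, haptoglobin, measured 3721, 1292 and 3723 in the knockouts and 1246 to 1452 in controls. Knockout 1 exceeded all controls in 19 of the 20 genes, knockout 3 in 18 and knockout 2 in 2. The median of the set was 0.35 without knockout 1 and 1.35 without knockout 2. Saa3, which macrophages also express, was the 1 gene that rose when adjusted over the list alone (adjusted p = 0.00142), and 0 passed over all genes. The complement list did not stand apart with all livers (adjusted p = 0.240) and was lower without knockout 1 (0.00529, where the highest over the refits was 0.851).

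**Figure D4:**
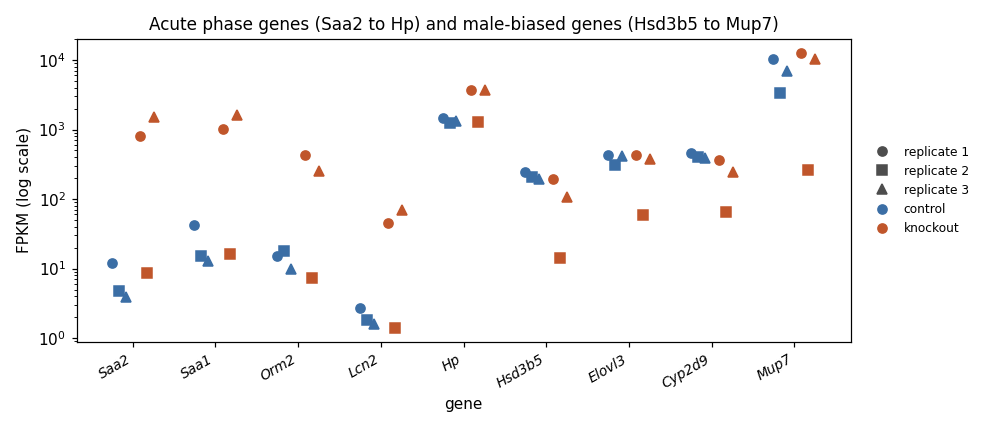
FPKM on a log axis (vertical) of 5 acute phase genes and 4 male-biased genes in 3 control and 3 knockout livers, one marker per liver. Saa2 and Saa1 were above 800 in knockouts 1 and 3 and below 50 in knockout 2 and the controls, and Hsd3b5 was at 14.0 in knockout 2 and above 100 in the other 5 livers.

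Markers of mesothelium, the cell layer on the liver surface, differed between the groups and also among the controls. Of 20 tested genes on the list written after the values were seen, 19 were higher in all 3 knockouts than in all 3 controls, and the median log2 change was 1.95; since the markers were chosen for this pattern, no test of the set is given. Msln, mesothelin, measured 2.02, 3.9 and 19.1 FPKM in controls 1 to 3 and 36.6, 60.7 and 41.8 in knockouts 1 to 3. Abundant markers were Igfbp6 (16.7 ± 15.1 against 95 ± 24.9), Gas6 (18.3 ± 10 against 47.9 ± 2.52) and Slpi (6.24 ± 5.49 against 50.5 ± 14). Control 3 was above both other controls in 20 of 20 markers. Without control 3, 58 genes passed the threshold, 50 of them higher, against 3 with all livers.

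**Figure D5:**
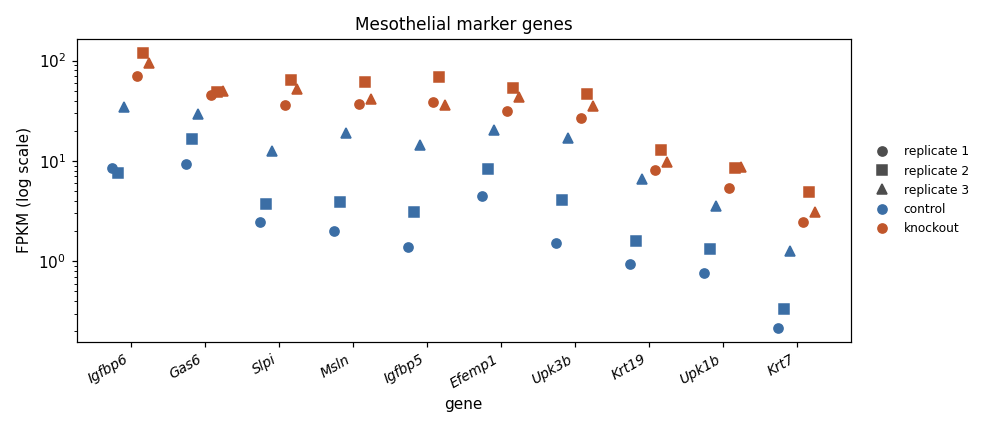
FPKM on a log axis (vertical) of 10 mesothelial marker genes in 3 control and 3 knockout livers, one marker per liver. Control 3 (triangles) lay above the other controls in each gene, and for Msln the controls were at 2.02 to 19.1 and the knockouts at 36.6 to 60.7.

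Stellate cell and fibroblast genes were higher in the knockouts (15 of 21 with higher means, median log2 change 0.36, adjusted p = 0.00156; adjusted p = 0.609 with an estimated correlation). Timp1 (0.915 ± 0.265 to 2.26 ± 0.331 FPKM) and Thy1 (0.441 ± 0.137 to 1.34 ± 0.404) rose when adjusted over the list alone. Acta2, smooth muscle actin, measured 2.33, 9.89 and 14.4 in knockouts 1 to 3 and 1.09 to 2.43 in controls, and Lox 0.358 ± 0.258 against 1.25 ± 0.790. Without knockout 2 the set did not pass (adjusted p = 0.127, from 3.19e-06 over the refits), and its median was 0.17 without control 1 and 0.63 without control 3, the control with the highest mesothelial markers. Bile duct and progenitor genes were higher (8 of 10 with higher means, median 0.15, adjusted p = 0.0335; adjusted p = 0.609 with an estimated correlation). The 4 that rose when adjusted over the list alone were Krt7 (0.606 ± 0.573 to 3.52 ± 1.27), Krt19 (3.07 ± 3.15 to 10.3 ± 2.35), Bicc1 (0.633 ± 0.394 to 2.56 ± 0.764) and Sox9. Krt7 and Krt19 are also on the mesothelial list, and control 3 was the highest control for both. Besides the block, this call was lost without knockout 3 (median 0.02, adjusted p = 0.151, from 0.00586), knockout 2 (median 0.31, 0.0585) or control 2 (0.0538), with quantile normalization (0.0566) and with scaling by total reads (0.113), and the median was 0.29 without control 1 and 0.03 without control 3.

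Antigen presentation genes were higher (9 of 14 with higher means, median log2 change 0.20, adjusted p = 0.0197; adjusted p = 0.595 with an estimated correlation). The class II genes H2-Eb1 (19.4 ± 5.34 against 34.8 ± 6.04 FPKM), H2-Aa (13.8 ± 3.64 against 23.1 ± 3.89), H2-DMb1 (1.82 ± 0.188 against 2.78 ± 0.553) and Cd74 (49.6 ± 13.2 against 78.7 ± 15.7) had the smallest p, with control 3 the highest control of each. The call was lost without knockout 3 (0.113, from 0.00805), and the median was 0.13 without control 3. Sinusoidal endothelial genes were lower (18 of 22, median -0.14, adjusted p = 0.0415; adjusted p = 0.609 with an estimated correlation), among them Cdh5 (6.01 ± 0.409 against 4.55 ± 0.272), Oit3 (10.5 ± 0.896 against 8.48 ± 0.339), Dnase1l3 (10.5 ± 2.22 against 7.67 ± 1.38) and Fcgr2b. That call was lost without knockout 3 (0.173, from 0.00418), control 1 (0.129) or control 2 (0.167), with quantile normalization (0.0612), scaling by total reads (0.0687) and a filter at 1 FPKM (0.0533). Red cell genes were lower (6 of 6, median -0.44, adjusted p = 0.0142; adjusted p = 0.609 with an estimated correlation), with Hba-a1 at 217 ± 33.4 against 124 ± 45.8, Hba-a2 at 89.9 ± 13.7 against 46.9 ± 17.8, Hbb-bs at 425 ± 48.0 against 284 ± 108 and Hbb-bt at 55.2 ± 4.92 against 47.7 ± 13.2. It was lost without knockout 2 (median -0.22, adjusted p = 0.0694, from 0.000521) and with no filter (0.0815), and the median was -0.68 without knockout 1. No gene of these 3 lists passed when adjusted over the list alone. Markers of Kupffer cells (adjusted p = 0.355), T and NK cells (0.198), B and plasma cells (0.134), neutrophils (0.134) and neighbouring organs (0.492) did not pass camera with all livers, while those of T and NK cells (0.00815) and neighbouring organs (0.042) passed fry's mixed test. By camera, neutrophil markers were higher with array weights (0.0273) and without control 3 (0.0163) or knockout 2 (0.00544, from a highest of 0.478), and those of neighbouring organs lower without knockout 2 (0.0304, from a highest of 0.873). Of the platelet and megakaryocyte markers 4 were tested, too few for camera, and Pf4 measured 2.66 ± 0.702 against 3.37 ± 1.11 FPKM.

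Transcripts of the mitochondrial genome were lower (11 of 13 with lower means, median log2 change -0.75, adjusted p = 0.000255; adjusted p = 0.609 with an estimated correlation). They took 7.19% ± 1.03 of reads in controls and 4.60% ± 0.947 in knockouts (two-sided exact permutation p = 0.1, the smallest that 3 against 3 livers can give). The named members mt-Nd5 (3080 ± 482 against 1678 ± 530 FPKM), mt-Nd6 (2488 ± 394 against 1324 ± 447), mt-Nd4 (4030 ± 738 against 2282 ± 684) and mt-Co2 (104 ± 23.6 against 62.8 ± 16.7) were lowest in knockout 2. Nuclear genes of oxidative phosphorylation were lower by less (24 of 29, median -0.12, adjusted p = 0.0116; adjusted p = 0.667 with an estimated correlation), for example Ndufs1 (14.2 ± 1.66 against 11.2 ± 0.782), Sdhc (62.1 ± 5.66 against 51.9 ± 3.54), Atp5a1 (384 ± 10.9 against 322 ± 14.8) and Sdha (126 ± 2.60 against 109 ± 2.95). With scaling by total reads their median turned to 0.02 (adjusted p = 0.188), and the call was also lost with quantile normalization (0.931, from 2.40e-05) and without control 2 (0.113), knockout 1 (0.0525) or knockout 3 (median -0.07, 0.221). No gene of either list passed when adjusted over the list alone.

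Ribosomal protein genes were higher (29 of 29 with higher means, median log2 change 0.18, adjusted p = 0.000681; adjusted p = 0.667 with an estimated correlation), among them Rps14 (408 ± 41.3 against 504 ± 39.2 FPKM), Rps3 (143 ± 12.2 against 181 ± 31.8), Rps2 (512 ± 24.8 against 611 ± 92.6) and Rps27 (175 ± 28.9 against 243 ± 77.9). Most of this change came from knockout 2: without it the median was 0.04 and the set did not pass (0.160, from 6.05e-07 over the refits), and without control 3 the median was 0.11. Proliferation genes were higher (16 of 19, median 0.15, adjusted p = 0.0264; adjusted p = 0.667 with an estimated correlation). The replication licensing genes Mcm2 (0.561 ± 0.0667 against 0.898 ± 0.0799), Mcm5 (1.35 ± 0.140 against 2.12 ± 0.607), Mcm3 (1.74 ± 0.230 against 2.13 ± 0.225) and Mcm6 (2.55 ± 0.606 against 3.38 ± 0.743) had the smallest p, while the mitotic kinase gene Aurka, chosen after its values were seen, measured 1.64 to 2.24 in controls and 1.13 to 1.90 in knockouts. That call was lost in 7 refits, with the highest p without control 3 (0.411, from 5.61e-05), and also without control 1 (0.104) or knockout 2 (median 0.06, 0.335), with array weights (0.198), scaling by total reads (0.156), quantile normalization (0.0612) and no filter (0.0570); the median was 0.28 without control 2 and 0.25 without knockout 3. No gene of these lists passed when adjusted over the list alone.

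The groups did not overlap on the first principal component, but they did on the second. The first principal component, with 40.8% of the variance, placed knockout 2 at 35.1, knockout 3 at 11.3 and knockout 1 at -0.31, and the controls at -25.6, -13.5 and -7.06. On the second (25.1%), knockouts 1 and 3 lay at -20.5 and -21.0, and knockout 2 at 16.5 with the controls at 4.68 to 13.4.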

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

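The voom fit and scaling by total reads were chosen after the data were seen. Of 491 values of the 26 named genes under the alternatives, 441 kept their direction and side of the threshold, 20 lost the call, 30 gained one and 0 reversed; Notch1 (log2 -0.34 to -1.12) and Thpo (-0.08 to -0.44) passed under none. The 3 gene calls (1 higher, 2 lower) became 1 call (0 higher, 1 lower) with a pseudocount of 0.1 or 0.01 FPKM and 0 (0 and 0) with no filter, where more genes were tested. Calls rose to 13 (5 higher, 8 lower) among protein-coding genes alone, 15 (4 and 11) with voom and 21 at an adjusted p under 0.10, and scaling by total reads gave 2 higher. With the replicate block there were 0 calls (0 higher, 0 lower), and it changed no other call than those given with the results. Leaving out 1 library gave 0 to 58 calls, 0 to 50 higher and 0 to 10 lower: 1 without control 1, 0 without control 2, 58 without control 3, 0 without knockout 1, 29 without knockout 2 and 2 without knockout 3; fewer samples are one cause of losses, and the cause of the other shifts was not tested. Quantile normalization left 7 lists lower; an estimated correlation and fry each left 0 higher and 0 lower. Scaling by total reads moved the median log2 change of all genes from -0.01 to 0.10, and median ratio scaling moved little because the deposited values already hold it. At this depth 3 reads in a gene 1 kilobase long are 0.150 to 0.201 FPKM. Simulated 2-fold changes were recovered in 27.0% of the 200 changed genes, not split by level.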

Other observations

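All tests in this part on the causes of a pattern were chosen after the results were seen. Outside the lists above, genes of glucose metabolism tended to lower values without passing as a set (17 of 27 with lower means, median log2 change -0.04, adjusted p = 0.0762), though they passed fry's mixed test (0.000391) and, by camera, with no filter (0.0374) and without control 1 (0.0206) or control 2 (0.0397), where the highest over the refits was 0.402. The median of this list ranged from -0.088 to 0.073 over the refits. Slc2a2, the hepatocyte glucose transporter, fell when adjusted over the list alone, from 32.4 ± 5.63 to 18.5 ± 2.22 FPKM (SD, n = 3). Pygl, glycogen phosphorylase, measured 78.1 ± 5.66 in controls and 56.2 ± 6.07 in knockouts, and Gys2, glycogen synthase, 36.1 ± 0.575 against 27.2 ± 3.51. G6pc, the last enzyme of glucose release, chosen after its values were seen, measured 272 ± 107 against 97.5 ± 60.5. In iron and heme metabolism, Alas1 fell and Tfrc rose when adjusted over the list alone (adjusted p = 0.00159 for each), and the list passed fry's mixed test (0.00377) but not camera (adjusted p = 0.884, median -0.0013 and mean 0.0045), with members that went both ways. Hamp, hepcidin, chosen after its values were seen, measured 1555, 850 and 904 in controls and 490, 1141 and 380 in knockouts.

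Mt1 and Mt2, the metallothioneins, rose when adjusted over their oxidative stress list alone, Mt1 from 48.1 ± 18.1 to 289 ± 145 FPKM, with knockout 2 lowest of the knockouts at 122; the set passed fry's mixed test (0.0119) but not camera (adjusted p = 0.394). Interferon genes were split: Gbp2 rose (3.18 ± 1.12 to 9.72 ± 2.97), and Rsad2 (3.07 ± 0.311 to 1.99 ± 0.158) and Ifit3 (10.5 ± 0.442 to 7.15 ± 1.07) fell when adjusted over the list alone, with the set at an adjusted p of 0.0605, and lower with no filter (0.0374), with scaling by total reads (0.0245) and without knockout 1 (0.0152) or knockout 3 (0.0497), where the highest over the refits was 0.366. Of the clock genes, Nr1d2 measured 3.62 ± 0.687 in controls and 2.18 ± 0.0670 in knockouts, and the set passed fry's mixed test (0.0451) but not camera (adjusted p = 0.781). The other lists did not pass camera with all livers: immediate early genes (0.0605), senescence and p53 (0.0744), heat shock (0.0762), amino acid and urea metabolism (0.132), lipid storage (0.152), mTOR and autophagy (0.270), inflammation (0.305) and endoplasmic reticulum stress (0.355). By fry's mixed test senescence and p53 (0.0256), mTOR and autophagy (0.0256) and lipid storage (0.042) passed. Several passed camera under other settings. With array weights, immediate early (0.023), senescence and p53 (0.0374) and endoplasmic reticulum stress genes (0.0374) were higher and amino acid and urea genes lower (0.0164). With voom immediate early genes were higher (0.04996), and with no filter senescence and p53 genes were higher and heat shock genes lower (0.0374 for each). Immediate early genes were higher without control 3 (0.00032, where the highest over the refits was 0.670) or knockout 1 (0.00077), and senescence and p53 genes without control 3 (0.0248, highest 0.630) or knockout 2 (0.0381). Heat shock genes were lower without control 2 (0.0136, highest 0.699), knockout 1 (0.0473) or knockout 2 (0.0475). Without knockout 2, endoplasmic reticulum stress genes were higher (0.000275, highest 0.709), and amino acid and urea (0.00171, highest 0.950) and lipid storage genes (0.0372, highest 0.690) lower. Without control 3, inflammation genes were higher (0.0358, highest 0.929). Around Wdfy1, 0 of the 5 nearby protein-coding genes tested had an unadjusted p under 0.05. Of all genes tested, 1670 of 12022 had such a p, so 0 of 5 says little about the region. The cause of the Wdfy1 difference was not tested.

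With 6 livers there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3 genes and the highest of the others 2, so 1 split gave as many; it gave 1670 genes at an unadjusted p under 0.05 and the highest of the others 891, and 21 genes at an adjusted p under 0.10 against at most 2. It gave 19 lists and the highest of the others 21, and 3 splits, the real one included, gave as many. Of the 3 other splits that part all same-numbered pairs, each gave 0 genes, and they gave 10, 21 and 13 lists.

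The acute phase transcripts were high in knockouts 1 and 3 and not in knockout 2. Whether knockout 2 is a mislabelled control was tested on the 29 genes with the smallest p between knockouts 1 and 3 and 2 controls. Knockout 2 lay beyond those controls on the knockout side in 20, 19 and 24 genes. The control held out (1, 2 or 3) did so in 22, 16 and 23, a lowest excess of -2, so this count cannot decide. In the same genes knockout 2 was nearer to the other knockouts than to those controls in 12, 15 and 20, and the held-out control in 7, 5 and 17. Bcl6, Cish and Wdfy1 also passed the threshold with knockout 2 left out. Knockout 2 measured 8.23, 0.295 and 0.584 FPKM in them, against 0.941 to 2.01, 3.38 to 5.14 and 4.39 to 4.87 in the controls. These 3 genes were picked because they passed with knockout 2 counted among the knockouts. Their values therefore cannot decide whether knockout 2 is a mislabelled control. Knockout 2 lay outside the controls in 15 of the 29 genes called without it, where 7.25 is expected for a control. The held-out controls above show that such counts can run high for a control, so this count cannot decide either. Knockout 2 exceeded all controls in 2 of 20 genes, which restates the pattern and so does not test whether Notch1 loss raises these transcripts. Notch1 itself measured 0.540 FPKM in knockout 2, above knockouts 1 and 3 (0.301 and 0.292) and below the controls (0.618 to 0.965). A gene-level value does not measure the deleted part, so this level cannot decide what knockout 2 is. A mislabelled knockout 2 was tested without a decision and stays open. A response to Notch1 loss that varies between animals, or an inflammation of knockouts 1 and 3 from another source, stays open too and was not tested.

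The growth hormone axis genes Cish, Socs2, Igf1 (chosen after its values were seen), Igfals and Ghr were lower and Bcl6 higher in the knockouts. Collection at another time of day is a candidate explanation. The median absolute change of 18 clock genes (0.21 in log2) lay at percentile 95.7 of 10000 lists matched on expression. With 2000 lists per left-out liver it lay at 93.4 to 99.1 in 5 of the 6 cases. Without control 2 it lay at 68.05, so the support depends on that liver. The measure ignores direction: 10 clock genes had higher and 8 lower means, and 0 passed when adjusted over the list alone. The lists were not matched on spread between livers, so the percentile cannot tell a shift in time from genes that vary more. A more fed state of the knockout mice may contribute, but it was tested on lipogenesis genes alone and that test was not decisive. Angptl8, named above as a hormone induced by feeding, was not part of that test. The lipogenesis median of 0.09 lay at percentile 98.8 of matched lists, while 14 of 23 genes were higher and camera did not call the list (adjusted p = 0.942). Without knockout 2 the median turned to -0.11, at percentile 9.6, and it was 0.03 without control 2 and 0.18 without knockout 1. Lists matched on expression need not share the correlation between genes, estimated at 0.15 for clock and 0.37 for lipogenesis genes, so both percentiles may overstate. A lower growth hormone signal in every knockout liver stays open too: the median of male-biased genes was -0.0066 from the controls in knockout 1, within the -0.32 to 0.44 that single controls differ from the other controls. The effect of Notch1 loss itself cannot be told apart from time or feeding, because neither is given for the mice.

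Mesothelial transcripts were high in the 3 knockouts and intermediate in control 3. More bile duct cells in the knockouts stay open as a source. The 8 bile duct and progenitor genes that the mesothelial list does not hold had a median log2 change of 0.057 and an upper quartile of 0.302. That quartile lay below the lower quartile of the mesothelial markers (1.63), but those markers were chosen for their change. Further, log2(FPKM + 1) compresses low genes, and Bicc1 (0.633 to 2.56 FPKM) and Sox9 (0.735 to 1.49) among the 8 rose when adjusted over their list alone. More liver surface in some of the tissue pieces and an effect of Notch1 loss in hepatocytes cannot be told apart: control 3 was above both other controls in 20 of 20 markers and 19 of 20 were higher in every knockout than in every control, but these counts restate the pattern on markers chosen for it. Of the 20 markers, 16 had a control mean of at least 1 FPKM and 2 (Krt7 and Krt19) are also on the bile duct list; no sort or gate was applied that would remove such cells.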
